A study of Mus musculus with 12 samples.

How the data were processed

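Hippocampal RNA of 7-month-old 5xFAD and WT mice was analysed from 2 deposited tables covering 12 libraries, 3 per group in 4 groups. Genotype, tissue and age came from the labels' characteristics, and the prefix (AT or CG) and replicate number from the sample titles. Per the labels' protocols, total RNA was extracted with TRIzol, rRNA was depleted with Ribo-Zero, libraries were made with a NEBNext Ultra kit and sequenced paired-end on a HiSeq, and an A-tailing preparation is named without detail. Per the submitters' processing notes, the genome build was mm9 and the tool DESeq, with no version. The aligner, junction caller, gene annotation and strand setting are not given in the sources used here.

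The CG table holds FPKM per gene (fragments scaled to transcript length and library size), as deposited by the authors, and neither its quantifier nor its denominator is given in the sources used here. FPKM is relative to each library's own total, so it shows shares, not amounts, and an exact 0 can be a failed estimate. Rpph1, a structured RNA, held 7.41% to 9.98% of total FPKM. Depth in reads is unknown for the CG libraries, but ratios of the lowest values between libraries gave their relative depth, 0.793 to 1.15 times that of WT replicate 1. The CG table lists 24318 genes, 5246 of them at 0 in every library.

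The AT table holds the deposited signal of each of 7025 mm9 intervals per library, with gene names, and the authors' own log2 ratio, p-value and adjusted p-value per interval, per the file headers. The intervals were taken as back-splice junctions from the design text and from their form, with up to 36 per gene. Within a library, 100% of the signal values were whole multiples of the smallest step within 0.01, so whole reads were recovered by dividing by that step, at 191408 to 695539 reads per library. A floor of 3 reads over a group corresponds to a signal of 0.265 in WT and 0.307 in 5xFAD. Only junctions that reach a signal of 2.03 in all 3 libraries of at least 1 group are listed, so junctions below that are outside every AT result. The deposited log2 ratio equals the log2 ratio of the group means with 0.1 added to each, and the deposited adjusted p equals the Benjamini-Hochberg adjustment of the deposited p over the listed junctions. The deposited p-values follow a formula that divides the difference of the group means by its standard error and reads the quotient against a normal distribution, which gave all 264 calls. No gene annotation of mm9 was used here, so exon or intron status is not stated for any interval, and the reference tables, which belong to another assembly, served only to look up older gene symbols.

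Each table was tested separately, because features and units differ between the tables. The main test was limma with a mean trend on log2(value + 1), over genes or junctions with a mean of at least 0.5, two-sided, with Benjamini-Hochberg adjusted p under 0.05. A fold change on this scale understates the change of low genes. This left 14500 genes in the 6 CG libraries, 14527 genes in the 5 without the library labelled 5xFAD replicate 3, and 7025 junctions. Before the data were examined, 26 gene lists were fixed for the cell types, glial states and pathways of this tissue, for contaminating tissue and for circular RNA biology. They were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and with fry beside it, adjusted over the lists, where at least 3 members were measured. The main design, the lists, the named-gene rule and most alternatives were fixed before the data were examined. The planned tests of AT against CG, of their interaction with genotype, and the fit of all 12 libraries were not run, since the tables share no feature and no unit.

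The named-gene rule always takes App, Thy1 and Gigyf2, and 1 more that is not reported here. It adds the 10 largest rises and 10 largest falls among called genes with a mean of at least 1 in the higher group and no overlap of the groups. Where fewer than 5 genes pass, it takes the 5 rises and 5 falls with the smallest unadjusted p instead. Of each list, up to 4 members with the smallest p may be named. Other genes named are said to be chosen after their values were seen. Per-library values of Cst7, Trem2, Gfap, Clec7a, C4b and Ttr in the CG account, the junctions described as most abundant, and the Fxr2 junction were chosen in that way.

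Software was R 4.3.3 with limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0. Counts were tested with edgeR's quasi-likelihood test and DESeq2 only on the recovered AT reads, as added alternatives. The limma fits and edgeR were tested on simulated data with 100 features changed 2-fold and 100 changed 4-fold before they were applied, while DESeq2, camera and fry were not tested in this way. Chi-square comparisons of recovered reads found every pair of AT libraries to differ by 5.85 to 13.5 per degree of freedom, and the correlations of log values ran from 0.617 to 0.893 in AT and from 0.969 to 0.990 in CG, so no 2 libraries were treated as 1 sample. The alternatives covered the pseudocount (0.1 and 0.5), the filter on low values, scaling, the variance model, the replicate number as a block, a fold threshold of 1.5, and each library left out in turn. Alternatives added after the data were seen are named with their results.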

Results

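RNA was measured in the hippocampus of 7-month-old 5xFAD and wild-type (WT) mice. The 5xFAD strain carries transgenes, human APP among them, with mutations of familial Alzheimer's disease, driven in neurons by regulatory sequence of Thy1. The 12 samples fell into 4 groups of 3, with WT and 5xFAD samples under each of the title prefixes AT and CG. The labels do not spell out these prefixes, and the design text names rRNA-depleted RNA-seq and an A-tailing RNA-seq with RNase R, an enzyme that degrades linear RNA and spares circles. The CG table gave the FPKM of 24318 genes, and the AT table gave the signal of 7025 intervals in mm9 coordinates, taken here as back-splice junctions, the joins that mark circular RNA. Total FPKM ran from 385214 to 412157 over the CG libraries, with 17221 to 17679 genes above 0 in each. The low FPKM values put the depth of the CG libraries at 0.793 to 1.15 times that of WT replicate 1. The AT libraries held 438790, 695539 and 695528 recovered junction reads in WT and 191408, 683540 and 659414 in 5xFAD. The labels do not say that the samples came from separate animals, so p-values measure the spread between these samples, which may be technical, wholly or in part. In CG, the sex-linked transcripts given below set replicate 1 of each genotype apart from the others, so replicate 1 came from a different animal.

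The first comparison asked which genes differed between 5xFAD and WT hippocampus in the CG libraries. Thy1, a neuronal surface glycoprotein whose regulatory sequence drives the transgenes, was among the genes fixed beforehand to be named. Its use as a check of the labels was not fixed beforehand. Its FPKM was 296, 308 and 340 in WT, and 1136 and 1172 in the libraries labelled 5xFAD replicates 1 and 2. The library labelled 5xFAD replicate 3 had 305 FPKM of Thy1, within the WT range, which goes against its label. The same library held WT levels of genes of activated glia. Cst7, an inhibitor of lysosomal proteases, was at 0.288, 0.243 and 0.295 FPKM in WT, 49.7 and 42.4 in 5xFAD replicates 1 and 2, and between the WT values in the library labelled 5xFAD replicate 3. Gfap, the intermediate filament of astrocytes, was at 118, 99.1 and 95.9 FPKM in WT, then 589, 449 and 106 in the libraries labelled 5xFAD. Trem2, a lipid receptor of microglia, was at 7.06, 5.55 and 6.77 FPKM in WT, then 71.0, 47.8 and 5.51. Every 6-library difference below includes this library under its label.

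**Figure D1:**
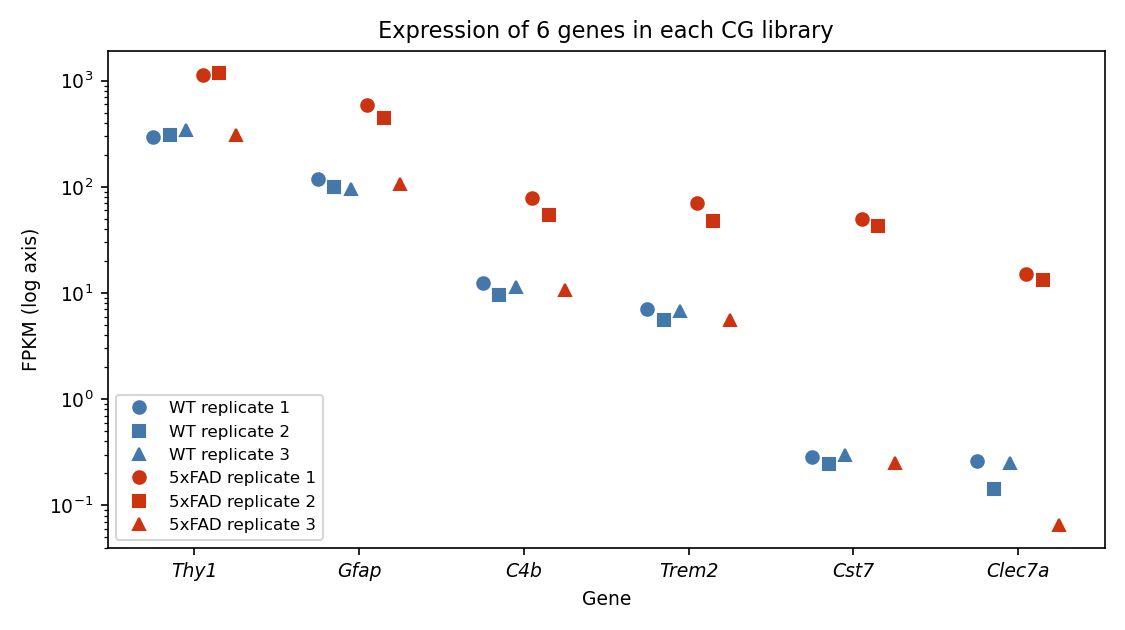
FPKM (log axis) of Thy1, Gfap, C4b, Trem2, Cst7 and Clec7a, with 1 point per CG library, WT in blue and 5xFAD in red, and the symbol giving the replicate. Each gene was high in the libraries labelled 5xFAD replicates 1 and 2, while the library labelled 5xFAD replicate 3 lay within or below the range of the 3 WT libraries, as for Gfap at 106 against 95.9 to 118 FPKM.

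Over all 6 CG libraries, limma called 1 of 14500 genes tested, Malat1, a long nuclear RNA. Malat1 was listed at 3608, 3288 and 3425 FPKM in the WT libraries and at 0 in all 3 libraries labelled 5xFAD (limma adjusted p = 9.51e-11). An exact 0 in a table of FPKM can be a failed estimate, and Malat1 was the only gene at 0 in all 3 5xFAD libraries with a WT mean above 5 FPKM. At an unadjusted p under 0.05, 424 genes were counted, and the second smallest limma adjusted p was 1.00. Thy1 averaged 315 ± 22.5 FPKM in WT (SD, n = 3) and 871 ± 490 FPKM in 5xFAD (SD, n = 3), a log2 difference of 1.24 (SE 0.47) that did not pass. App differed by -0.05 (SE 0.11) and Gigyf2, a translational repressor, by -0.07 (SE 0.09) on the log2(FPKM + 1) scale, neither past the test. The table names the mouse genes, and whether transgene reads were assigned to App is not given in the sources used here.

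Genes with the smallest p after Malat1 did not pass either. Of the higher ones, Ang, a ribonuclease, was at 1.92, 1.01 and 1.74 FPKM in WT and 4.81, 4.46 and 3.79 in 5xFAD, a log2 difference of 1.08 (SE 0.17). Spp1, a secreted phosphoprotein of activated microglia, averaged 3.74 ± 0.795 FPKM in WT and 9.50 ± 3.35 in 5xFAD (SD, n = 3 each). The log2 differences of Anxa2, Plekho1 and Cd34 were 0.62, 0.59 and 0.49. On the lower side, Sln, Hes1, Ghr and Alg12 differed by -1.04, -0.52, -0.47 and -0.35. In simulated data of the same spread, the 6-library limma fit recovered 73% of genes changed 2-fold and 97% of those changed 4-fold. The simulation changed all 3 5xFAD libraries alike. These shares therefore do not hold for genes at WT levels in the library labelled 5xFAD replicate 3.

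Gene lists fixed beforehand were tested over the 6 libraries as well. Of 26 lists, camera with its preset correlation called 14, 12 of them higher in 5xFAD and 2 lower. The highest shift was in plaque-associated microglia, genes that microglia switch on around amyloid deposits, where 20 of 20 members had positive differences with a median log2 difference of 1.30 (camera adjusted p = 1.33e-24, and adjusted p = 0.272 with an estimated correlation). Complement genes had a median of 1.06 with 11 of 11 positive (camera adjusted p = 7.39e-16, adjusted p = 0.272 with an estimated correlation). Lysosomal genes had a median of 0.83 with 16 of 16 positive (camera adjusted p = 1.69e-16, adjusted p = 0.272 with an estimated correlation). Antigen presentation genes had a median of 0.81 with 10 of 10 positive (camera adjusted p = 7.67e-09, adjusted p = 0.272 with an estimated correlation). Interferon response genes had a median of 0.79 with 12 of 12 positive (camera adjusted p = 2.25e-10, adjusted p = 0.300 with an estimated correlation). Homeostatic microglia genes had a median of 0.65 with 12 of 12 positive (camera adjusted p = 3.91e-14, adjusted p = 0.272 with an estimated correlation). Reactive astrocyte genes had a median of 0.51 with 10 of 10 positive (camera adjusted p = 1.87e-08, adjusted p = 0.272 with an estimated correlation). In the library labelled 5xFAD replicate 3 the medians of these 7 lists lay between -0.19 and 0.12 relative to the WT mean.

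Smaller shifts were called in cholesterol metabolism, with a median of 0.22 and 13 of 15 positive (camera adjusted p = 8.41e-09, adjusted p = 0.272 with an estimated correlation). Cytosolic ribosomal protein genes had a median of 0.15 with 32 of 34 positive (camera adjusted p = 8.41e-09, adjusted p = 0.442 with an estimated correlation, and 0.0549 by camera without WT replicate 2). Oligodendrocyte and myelin genes had a median of 0.15 with 11 of 12 positive (camera adjusted p = 0.000415, adjusted p = 0.376 with an estimated correlation, and 0.185 by camera without 5xFAD replicate 2). Astrocyte identity genes had a median of 0.11 with 9 of 10 positive (camera adjusted p = 0.00185, adjusted p = 0.308 with an estimated correlation, and 0.145 by camera without WT replicate 1). Blood genes had a median of 0.23 with 5 of 6 positive (camera adjusted p = 0.0481, adjusted p = 0.487 with an estimated correlation). The blood call also ended by camera without WT replicate 1 (adjusted p = 0.703), WT replicate 2 (0.0549), 5xFAD replicate 2 (0.477) and the library labelled 5xFAD replicate 3 (0.417), and with no filter on low values (0.120), limma without the mean trend (0.0608) and array quality weights (0.199). The lower lists were inhibitory neurons, with a median of -0.16 and 3 of 11 positive (camera adjusted p = 0.0120, adjusted p = 0.272 with an estimated correlation, and 0.249 by camera without 5xFAD replicate 1), and synapse. Synapse genes had a median of -0.08 with 1 of 19 positive (camera adjusted p = 0.0130, adjusted p = 0.442 with an estimated correlation). The synapse call ended by camera without WT replicate 2 (adjusted p = 0.355) and without 5xFAD replicate 2 (adjusted p = 0.264).

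The other 12 lists were not called by camera over the 6 libraries. These were transgene-linked genes (adjusted p = 0.215), amyloid processing (0.865), excitatory neurons of the hippocampus (0.531), immediate early genes (0.150), stress and unfolded protein response (0.773), oligodendrocyte precursors (0.529), vessel cells (0.559), neighbouring brain regions (0.675), hosts of abundant brain circular RNAs (0.470), circular RNA biogenesis and decay factors (0.621), oxidative phosphorylation (0.219), and choroid plexus and ependyma (0.0595). The camera direction was up for amyloid processing, whose median was -0.01, and for the stress list, whose median was -0.05 and mean 0.02. Choroid plexus genes had a median of -0.51, and WT replicate 1 stood apart in them: Ttr, a thyroid hormone carrier made by choroid plexus, was at 2758 FPKM there, 32.9 and 55.6 in the other WT libraries, 48.2 and 62.6 in 5xFAD replicates 1 and 2 and 467 in the library labelled 5xFAD replicate 3. No list member passed limma over all genes tested. Adjusted over the list alone, 10 of 11 complement genes and 1 of 20 plaque-associated genes (Spp1) passed, and 0 in each of the other lists. Fry, which tests whether a list moves 1 way on balance, called 0 lists.

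With 1 library left out or another setting, camera called 6 of these 12 lists. Without 5xFAD replicate 1 it called immediate early genes (adjusted p = 4.28e-08) and neighbouring brain regions (0.0337) higher, and vessel cells (0.00109) and oxidative phosphorylation (0.0136) lower. Oxidative phosphorylation was also called lower without WT replicate 2 (5.77e-07) and with array quality weights (0.0431), and immediate early genes higher with those weights (0.000657). Transgene-linked genes were called higher without the library labelled 5xFAD replicate 3 (0.0149). That list of 3 genes had a median of 0.08 and a mean of 0.63 there, and its 1 called member was Thy1, so its call restates Thy1. Choroid plexus genes were called higher without WT replicate 1 (0.0291), and lower without WT replicate 2 (0.000100), without WT replicate 3 (0.0171), without the library labelled 5xFAD replicate 3 (0.00891) and with quantile normalization (0.0498).

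**Figure D2:**
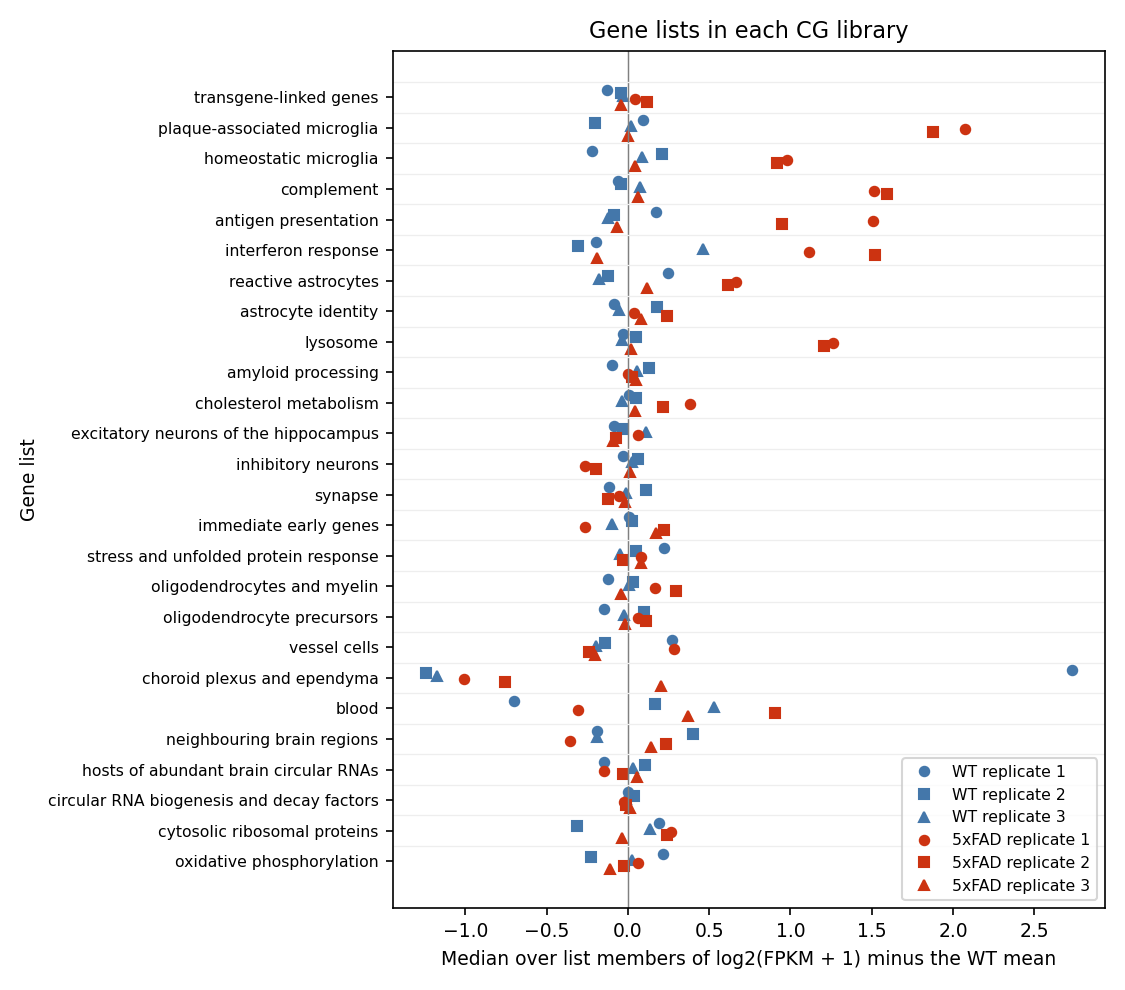
Median over each gene list's members of log2(FPKM + 1) minus the WT mean (horizontal axis), with 1 point per CG library, WT in blue and 5xFAD in red, for 26 lists (vertical axis). Each WT library was set against the mean of the other WT libraries only. Plaque-associated microglia stood at 2.07 and 1.88 in the libraries labelled 5xFAD replicates 1 and 2 and at 0.00 in replicate 3, and choroid plexus genes stood at 2.73 in WT replicate 1.

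The planned series of fits that each left out 1 library included a fit without the library labelled 5xFAD replicate 3. It is described here because of what the data showed, so its 5xFAD arm of 2 libraries was not chosen blind. In these 5 libraries limma called 174 of 14527 genes, 172 higher in 5xFAD and 2 lower, with 858 at an unadjusted p under 0.05. Each of the other 5 fits without 1 library called only Malat1. Thy1 rose by 1.87 on the log2 scale (SE 0.13, limma adjusted p = 0.000676), from 315 ± 22.5 FPKM in WT (SD, n = 3) to 1154 ± 25.7 in 5xFAD (SD, n = 2). App (-0.06, SE 0.13) and Gigyf2 (-0.13, SE 0.10) did not pass. The named-gene rule set for the 6-library fit was applied here after the data were seen.

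Genes of plaque-associated microglia made up 9 of the 10 largest rises in the 5 libraries. Cst7 rose by 5.20 (SE 0.13, limma adjusted p = 6.43e-06), from 0.275 ± 0.0284 FPKM in WT (SD, n = 3) to 46.1 ± 5.16 in 5xFAD (SD, n = 2). Clec7a, a receptor for fungal glucans, rose by 3.64 (SE 0.14) and Itgax, an integrin subunit, by 2.71 (SE 0.21). Trem2 rose by 3.00 (SE 0.19) and its signalling adaptor Tyrobp by 2.90 (SE 0.23). Lyz2, a lysozyme, rose by 3.18 (SE 0.14), Cd52 by 3.33 (SE 0.23), and the chemokines Ccl3 and Ccl6 by 3.05 (SE 0.15) and 2.78 (SE 0.16). Limma adjusted p-values of these 8 genes ran from 9.97e-05 to 0.00139. Pisd-ps1, a pseudogene, rose by 3.85 (SE 0.25), from 0.0312 ± 8.02e-05 FPKM in WT to 14.5 ± 6.50, and its reads could be shared with near-identical copies. Its value was 0.0312, 0.0312 and 0.0313 FPKM in WT and 0.0313 in the library labelled 5xFAD replicate 3. Values this even across libraries of differing depth can be a floor of the estimate, so the size of the rise is uncertain. Of the 20 plaque-associated genes, 15 were called higher over all genes and 20 adjusted over the list alone (camera adjusted p = 1.36e-60, adjusted p = 0.0587 with an estimated correlation).

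Other glial lists had called members in the same libraries. The RNA came from hippocampal tissue. For these lists and the plaque-associated one, more glial cells therefore cannot be told apart from higher expression per cell. Of 12 homeostatic microglia genes, which mark microglia at rest, 6 were called higher and 12 adjusted over the list alone (camera adjusted p = 3.03e-25, adjusted p = 0.0789 with an estimated correlation). Fcrls rose by 1.71, the growth factor receptor Csf1r by 1.32, Olfml3 by 1.29 and Selplg by 1.01. Of 11 complement genes, 7 were called higher and 11 adjusted over the list alone (camera adjusted p = 1.83e-31, adjusted p = 0.0219 with an estimated correlation). C1qa, C1qb and C1qc, the chains of the first complement component, rose by 2.29, 2.12 and 2.24. C4b rose by 2.45 (SE 0.18), and it has a near-identical neighbour, C4a, that could share its reads. Of 16 lysosomal genes, 9 were called higher and 13 adjusted over the list alone (camera adjusted p = 3.09e-38, and still passing with an estimated correlation), with Mpeg1 up by 2.57, Cd68 by 2.51 and the protease Ctss by 2.29. Of 10 reactive astrocyte genes, 4 were called higher and 5 adjusted over the list alone (camera adjusted p = 2.75e-12, adjusted p = 0.0587 with an estimated correlation). Gfap rose by 2.30 (SE 0.16), from 104 ± 11.7 FPKM in WT (SD, n = 3) to 519 ± 98.9 in 5xFAD (SD, n = 2), with the protease inhibitor Serpina3n up by 1.40, Vim by 1.37 and the cytokine receptor Osmr by 1.32.

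The antigen presentation and interferon lists had called members as well. Of 10 antigen presentation genes, 4 were called higher and 8 adjusted over the list alone (camera adjusted p = 5.27e-18, adjusted p = 0.0919 with an estimated correlation). Cd74 rose by 2.70 (SE 0.40), and the class I genes H2-D1, B2m and H2-K1 rose by 1.86, 1.69 and 1.44, with H2-D1 and H2-K1 similar enough to share reads. Of 12 interferon response genes, 7 were called higher and 12 adjusted over the list alone (camera adjusted p = 3.03e-25, adjusted p = 0.0919 with an estimated correlation). Bst2 rose by 1.59, Oasl2 by 1.52, Ifit3 by 1.45 and Ifitm3 by 1.32. Eif2ak2, a kinase that binds double-stranded RNA and is bound by circular RNAs, differed by 0.68 (SE 0.14, limma adjusted p = 0.0976) and did not pass over all genes, though it was the 1 member of the 23 circular RNA biogenesis and decay factors called adjusted over the list alone. With array quality weights Eif2ak2 passed over all genes (limma adjusted p = 0.0431).

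In contrast, neuronal genes gave small differences in the 5 libraries, and no neuronal list member passed limma. Inhibitory neuron genes had a median of -0.20 (camera adjusted p = 0.00387, adjusted p = 0.132 with an estimated correlation), with Gad1, the main enzyme of GABA synthesis, at 114 ± 11.9 FPKM in WT (SD, n = 3) and 88.6 ± 7.70 in 5xFAD (SD, n = 2). Synapse genes had a median of -0.08 (camera adjusted p = 0.0183, adjusted p = 0.472 with an estimated correlation). The inhibitory neuron call ended by camera without 5xFAD replicate 1 (adjusted p = 0.0753), and the synapse call without WT replicate 2 (0.164), without 5xFAD replicate 2 (0.445) and with array quality weights (0.0726). The excitatory neuron list was not called, with a median of -0.01 (camera adjusted p = 0.979). The falls were Malat1 and Dcn, a proteoglycan of connective tissue, which fell by 0.79 (SE 0.13, limma adjusted p = 0.0355). Dcn stood at 28.7 FPKM in the library labelled 5xFAD replicate 3 and lost its call in 6 of 16 alternatives.

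Of all 26 lists, camera called 15 in the 5 libraries, 12 higher and 3 lower, and with an estimated correlation 2, complement and lysosome. Fry called 9. The 6 called lists not yet given for this fit were ribosomal proteins (camera adjusted p = 3.21e-11, adjusted p = 0.407 with an estimated correlation), cholesterol metabolism (9.69e-09, and 0.0962), myelin (2.73e-05, and 0.132), transgene-linked genes (0.0149, and 0.174), astrocyte identity (0.0157, and 0.472) and, lower, choroid plexus (0.00891, and 0.580). The choroid plexus call ended by camera without WT replicate 1 (adjusted p = 0.962), without 5xFAD replicate 1 (0.0732) and with array quality weights (0.180). The transgene-linked call, with Thy1 as its 1 called member, ended by camera without WT replicate 1 (adjusted p = 0.0563). That of astrocyte identity ended without WT replicate 1 (0.238) and without 5xFAD replicate 2 (0.466). Of the lists not called, camera gained oxidative phosphorylation, lower, without WT replicate 2 (0.00171), hosts of abundant brain circular RNAs, lower, without WT replicate 1 (0.0206) and without 5xFAD replicate 2 (0.0355), and blood, higher, without WT replicate 3 (0.0470), without 5xFAD replicate 1 (0.000404), with the replicate block (0.00215) and with a term for Y-linked transcripts (0.0178). Vessel cells were called lower without 5xFAD replicate 1 (0.0103) and higher without 5xFAD replicate 2 (0.0224), and immediate early genes higher without the first (4.42e-06) and lower without the second (0.000462). The count of called genes also depended on which further library was left out, at 106 without WT replicate 2, 84 without WT replicate 3, 35 without 5xFAD replicate 1 and 52 without 5xFAD replicate 2, the last pair assuming that the lone 5xFAD library varied like the others. Of the genes named, Csf1r and Olfml3 lost their call without 5xFAD replicate 1, and Selplg, Cd74, H2-K1, Bst2, Oasl2, Ifit3, Ifitm3, Serpina3n, Vim and Osmr lost theirs in 2 to 7 of the 16 alternatives, with limma adjusted p-values up to 0.339. Simulated data of the same spread gave a recovery of 57% of 2-fold and 88% of 4-fold changes in this fit.

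The second comparison concerned back-splice junctions in the AT libraries. The 7025 junctions lay on 20 chromosomes with a median length of 9516 bp, 230 of them with no gene named and the others in 2947 genes. Dgki, a diacylglycerol kinase, had the most junctions, 36, followed by Tasp1 with 23 and Nbea with 22. Values were whole multiples of 1 read in 100% of entries within 0.01, so reads could be recovered. A single read was worth a signal of 0.228 to 0.374 in WT and 0.226 to 0.866 in 5xFAD. Junctions at 0 numbered 570, 24 and 167 in WT and 586, 33 and 68 in 5xFAD, with the most in the libraries with the fewest reads. Counting error alone sets the floors given here, since no molecular identifiers are stated.

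The most abundant junction was that of Gigyf2 on chromosome 1, from 89260678 to 89276583 (mm9), first in 5 of 6 AT libraries. Its signal was 2384, 3194 and 2785 in WT and 2334, 2884 and 2751 in 5xFAD, or 2788 ± 405 against 2656 ± 287 (SD, n = 3 each). The log2 difference was -0.07 (SE 0.24, 95% interval -0.58 to 0.45, limma adjusted p = 0.990), smaller than the spread between replicates. The other 5 Gigyf2 junctions were far less abundant. That from 89260678 to 89270686 averaged 104 ± 14.7 in WT and 78.2 ± 20.4 in 5xFAD, a difference of -0.43 (SE 0.32). That from 89230844 to 89261854 had 13.1, 4.56 and 5.61 in WT and 0, 1.36 and 0 in 5xFAD, a difference of -2.59 (SE 0.62, limma adjusted p = 0.383) that did not pass. Which of these intervals the design text calls circGigyf2 was not matched here, and its knockdown in CAD cells was not analysed here.

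Behind Gigyf2, the junctions of Med13l (chromosome 5, 119043341 to 119043579), Phf21a (chromosome 2, 92054205 to 92070881) and Ksr2 (chromosome 5, 117950721 to 117955648) had the highest mean signal. Med13l, a subunit of the Mediator kinase module, averaged 1418 ± 278 in WT and 1534 ± 946 in 5xFAD (SD, n = 3 each) and ranked first in 5xFAD replicate 1. Phf21a, a chromatin reader, averaged 1191 ± 89.7 and 1258 ± 212, and Ksr2, a kinase scaffold, 1038 ± 195 and 1122 ± 448. Among the 10 most abundant junctions, log2 differences ran from -0.23 for Ssbp2 to 0.07 for Phf21a, each below its SE. The 10 junctions with the highest signal within each library, which can differ between libraries, took 7.26% to 8.67% of its signal.

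**Figure D3:**
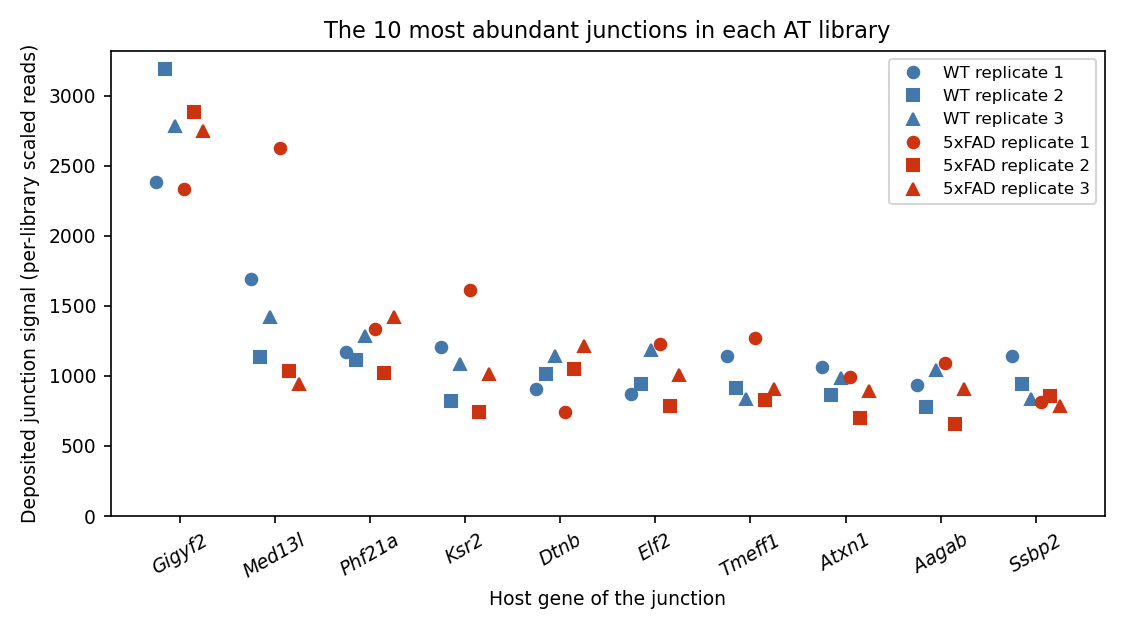
Deposited signal (reads scaled per library, linear axis from 0) of the 10 junctions with the highest mean, named by host gene, with 1 point per AT library, WT in blue and 5xFAD in red. The Gigyf2 junction stood between 2334 and 3194 in all 6 libraries, and the Med13l junction reached 2625 in 5xFAD replicate 1.

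Between 5xFAD and WT, limma called 0 of 7025 junctions, with 399 at an unadjusted p under 0.05 and a smallest adjusted p of 0.368. On recovered reads, edgeR called 0 of 6911 (166 at an unadjusted p under 0.05), and DESeq2 called 1, Uap1 (235 at an unadjusted p under 0.05). Limma with array quality weights called 2, Uap1 and Cdkal1. The power was low: in simulated data the limma fit recovered 0% of 2-fold and 6% of 4-fold changes, edgeR 1% and 19%, and the biological coefficient of variation was 0.528.

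The 10 junctions with the smallest p in either direction, none past limma, were mostly absent from a whole group. The Uap1 junction (chromosome 1, 172079401 to 172097079) is from a gene of amino sugar synthesis. It had 0 reads in all 3 WT libraries and 4, 29 and 39 in 5xFAD. Its 5xFAD mean was 24.4 times a floor of 3 reads over the WT group (DESeq2 adjusted p = 0.0207, edgeR adjusted p = 0.976). Such ratios to a floor allow for counting error only. They leave out the spread between replicates and come from junctions picked for a small p, so they are no lower bounds. Also at 0 in WT were Cdkal1 (chromosome 13, 29717489 to 29809686, 5xFAD mean 16.9 times the WT floor) and Wdfy3 (chromosome 5, 102301850 to 102305028, 10.9 times). Mga (chromosome 2, 119747101 to 119747578) had 2 WT reads in all. At 0 in 5xFAD were Creb1 (chromosome 1, 64612790 to 64620829, 8, 14 and 17 reads in WT) and Pip4k2b (chromosome 11, 97583675 to 97594069, WT mean 10.9 times the 5xFAD floor). Single reads in 5xFAD were found for Tgfbr3 (chromosome 5, 107566548 to 107578977), Dmd (chromosome X, 80381966 to 80626696) and Scyl3 (chromosome 1, 165863609 to 165866662). Across all junctions, 7 were at 0 in all 3 WT libraries and 2 in all 3 5xFAD libraries.

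Of the transgene-linked genes, App had 6 junctions and Thy1 had 0 listed, so the labels of the AT libraries could not be checked by Thy1. The most abundant App junction (chromosome 16, 85013871 to 85030610) averaged 140 ± 33.1 in WT and 154 ± 9.56 in 5xFAD (SD, n = 3 each), and that from 85056568 to 85083133 had 0, 2.51 and 0 in WT and 5.20, 3.16 and 2.63 in 5xFAD, neither past limma. Lists could be tested only where at least 3 junctions came from their genes, which left 7. Camera called 0 of these, and 0 junctions were called adjusted over any of these lists alone. The adjusted p was 0.288 for transgene-linked genes (6 App junctions), 0.288 for synapse (40 junctions), 0.302 for oxidative phosphorylation (4), and 0.948 for amyloid processing (4), excitatory neurons (5), hosts of abundant brain circular RNAs (107) and circular RNA biogenesis and decay factors (25). The last list's median of 0.03 and mean of -0.09 differed in sign, and the host list's median of -0.04 and mean of -0.03 lay opposite to its camera direction. Without AT WT replicate 1, camera called 2, synapse lower and oxidative phosphorylation higher, both at adjusted p = 0.0347. Among synapse members, a Grin2b junction (chromosome 6, 135993908 to 135994337) from an NMDA receptor subunit differed by -1.62 (SE 0.64), and a Dlgap1 junction (chromosome 17, 70932407 to 71012149) of the host list by -1.61 (SE 0.63), neither past limma.

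The authors' deposited table gave its own test of the same junctions and called 264 of 7025 at an adjusted p under 0.05, 107 higher and 157 lower in 5xFAD. In the authors' deposited table the Gigyf2 junction from 89260678 to 89276583 had a log2 ratio of -0.07 and an adjusted p of 0.973. The Cdkal1, Wdfy3, Creb1 and Tgfbr3 junctions above had adjusted p-values of 1.69e-209, 1.86e-66, 1.20e-26 and 7.09e-19 in the authors' deposited table. A junction of Rbfox1 (chromosome 16, 7294162 to 7353157), a splicing factor, had a log2 ratio of -1.94 and an adjusted p of 0.00904 in the authors' deposited table. A junction of Fxr2 (chromosome 11, 69465809 to 69466064), with 0 reads in WT and 3, 11 and 10 in 5xFAD, was listed with a p of 0 in the authors' deposited table. The signs of the ratio in the authors' deposited table and of the limma difference were the same for 90.2% of junctions. Of the 264 calls in the authors' deposited table, 160 were among the 399 junctions with an unadjusted limma p under 0.05, against 15.0 for independent lists, though both tests read the same libraries. Of the same 264 in the authors' deposited table, 0 passed limma after adjustment and 80 had an unadjusted edgeR p under 0.05, against 166 of all 6911 junctions that edgeR tested.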

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

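The tests on recovered reads, the Welch and normal references, the term for Y-linked transcripts and every alternative of the 5-library fit were chosen only after the data were seen. In the 6 CG libraries the count of genes was 1 (Malat1) under each alternative, except without the library labelled 5xFAD replicate 3, so that leaving out a library gave 1 to 174. In the 5 libraries the 174 genes ranged from 35 to 174 when a further library was left out, where fewer samples carry the test, and from 128 to 257 under the others, the highest with array quality weights. For AT junctions the count of 0 became 2 with array quality weights, 1 with DESeq2 and 264 with the normal reference, and stayed from 0 to 0 with any library left out. The authors' deposited table gave 169 calls at 0.01 and 356 at 0.1, and the Welch reference on the same values gave 0 (244 at an unadjusted p under 0.05). The 14 CG lists became 0 with an estimated correlation and 0 with fry, and 11 to 17 with a library left out. In the 5 libraries the 15 lists became 2 with an estimated correlation, 9 with fry and 13 to 16 with a further library left out. The AT lists gave 0 to 2 with a library left out, the 2 without AT WT replicate 1.

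The choroid plexus list turned from lower to higher without WT replicate 1 in the 6 libraries (camera adjusted p = 0.0291) and in the 5 (0.962). In the 5 libraries vessel cells were called lower without 5xFAD replicate 1 (camera adjusted p = 0.0103) and higher without 5xFAD replicate 2 (0.0224), and immediate early genes higher without 5xFAD replicate 1 (4.42e-06) and lower without 5xFAD replicate 2 (0.000462). With 1 library left out, the camera adjusted p ranged from 0.000100 to 0.481 for choroid plexus in the 6 libraries. In the 5 it ranged from 5.69e-06 to 0.962 for choroid plexus, from 0.0103 to 0.834 for vessel cells and from 4.42e-06 to 0.979 for immediate early genes. The cause was not tested beyond the library that was left out.

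The replicate numbers did not pair the samples by the rule set: same-numbered CG libraries had deviation correlations of 0.415, 0.279 and 0.0398, and AT libraries 0.0676, 0.0884 and 0.0401. 5xFAD replicates 1 and 2 correlated best with the WT library of their own number, and 5xFAD replicate 3 with WT replicate 2 (0.147 in CG, 0.0815 in AT). The tests of AT against CG, of their interaction and of all 12 libraries in 1 fit were not run. With the replicate number as a block, the counts were 1 CG gene, 201 genes in the 5 libraries, 0 AT junctions, 14 lists, 16 lists in the 5 libraries and 0 AT lists. Depth limits the AT libraries most in 5xFAD replicate 1, where 191408 reads were recovered and 1 read is worth a signal of 0.866.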

Other observations

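The tests of the library labelled 5xFAD replicate 3 and of the normal reference, and the splits behind the counts of CG genes, of AT junctions and of calls by the deposited formula, were chosen or written only after the result was seen. Genes called in the 5-library fit reached beyond the fixed lists: of 174 calls, 53 were in a list and 121 in none, 119 of these higher in 5xFAD. Those named here were picked after their values were seen. Ly86, which associates with a receptor of B cells and macrophages, was at 6.71, 7.29 and 7.95 FPKM in WT, 32.4 and 38.2 in 5xFAD replicates 1 and 2 and 7.64 in the library labelled 5xFAD replicate 3. Fcgr2b rose by 2.51 and Fcer1g by 2.12 on the log2 scale. The pattern receptors Cd14 and Tlr2 rose by 1.78 and 1.44, the myeloid transcription factor Irf8 by 1.70, the phosphatase Ptprc by 1.60 and the inhibitory receptor Lag3 by 2.06. Fcgr2b resembles other Fcgr genes, so its reads cannot be assigned with certainty.

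A second structure ran across genotype. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty summed to 63.3 FPKM in CG WT replicate 1 and 56.7 in 5xFAD replicate 1, where Xist was at 0.246 and 0.136 FPKM. In each other CG library they summed to at most 0.0204, with Xist at 99.9 to 112 FPKM. This is the pattern of male RNA in the replicate 1 libraries and of female RNA in the others. Sex cannot be told apart from other traits of the replicate 1 libraries. Setting the 2 replicate 1 libraries against the other 3 of the 5-library fit called 173 genes by limma, 26 higher in replicate 1, and 0 of these were shared with the 174 genotype calls. Besides the Y-linked genes and Xist, Rbm3, an RNA-binding protein induced by cold, was at 88.0 and 91.6 FPKM in the replicate 1 libraries and 44.3, 35.1, 34.8 and 33.4 in the others. Igip was at 26.2 and 23.9 FPKM against 58.0, 57.2, 54.6 and 52.3, and the long non-coding RNA Tug1 at 18.7 and 20.1 against 39.6, 36.4, 34.5 and 35.9. With a term for Y-linked transcripts the 5-library fit called 194 genes, 160 of them among the 174.

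The CG library labelled 5xFAD replicate 3 had WT levels of Thy1 and of the medians of glial lists, but not of every gene. Malat1 was at 0 there, as in the other 5xFAD libraries, against 3288 to 3608 FPKM in WT, and Ang was at 3.79 FPKM, against 1.01 to 1.92 in WT and 4.46 and 4.81 in the other 5xFAD libraries. Both were picked after their values were seen and for small p-values in a fit that counts this library as 5xFAD, so they do not support its label, and the 0 of Malat1 can be a failed estimate. A swap with a CG WT library is argued against by the plaque-associated list. Its highest median in a WT library was 0.0951 on the log2 scale relative to the other WT libraries. The other 5xFAD libraries stood at 2.07 and 1.88 relative to the WT mean. A carrier that expresses the Thy1-driven cassette without a glial response is argued against too, with Thy1 at 0.898 times the highest WT library. A mixture with at least 10% of RNA like that of the other 5xFAD libraries is argued against as well. Over 91 members of 7 glial lists the median share of such RNA on the FPKM scale was -0.00264, within the -0.0194 to 0.00703 of the WT libraries. Its upper 95% bootstrap bound was 0.0115, which treats the members as independent and can be too low where they move together. The share and the Thy1 ratio use levels that were seen before these tests were written. They set limits on these 2 sources and are no independent evidence. RNA of a sample without the transgenes under a 5xFAD label and a carrier with a silent cassette cannot be told apart here. The glial levels were seen first, so the library's median position on the log2 scale between WT (0) and the other 5xFAD libraries (1), 0.0106 with an upper bound of 0.0257, only restates them. A smaller share of 5xFAD RNA and a biological difference between animals stay open too.

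The 264 calls of the authors' deposited table stand against 0 by limma. A candidate explanation is the normal reference, which makes no allowance for 3 libraries per group: junctions simulated with no difference gave 254 calls of 5929 by the same formula, with 13.5% at an unadjusted p under 0.05, and the Welch reference on the deposited values gave 0 calls. The called junctions had a median of 78 reads over all libraries, against 179 for the others. By the same formula the real split gave 264 and the highest other split 535, 2 of the 10 splits as large. That of 535 set WT replicates 1 and 3 and 5xFAD replicate 1, the libraries with the most junctions at 0, against the rest. Why it gave more calls was not tested. A difference between genotypes in some of the 264 junctions stays open. That 80 of them had an unadjusted edgeR p under 0.05 gives it no support, since the 264 were picked on the same libraries. Of all 6911 junctions tested by edgeR, 166 had such a p.

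The 10 splits of 6 or 5 libraries are too few for a share under 0.05. For CG genes the real split gave 1 and the highest other 1, with 4 splits as large. For AT junctions limma gave 0 in the real split and in the highest other, 10 splits as large, with 399 at an unadjusted p under 0.05 in the real one. For CG lists the real split gave 14 and the highest other 15, which set WT replicate 1 with 5xFAD replicates 1 and 2, and 3 splits were as large. The other splits with 13, 14 or 15 lists each kept 5xFAD replicates 1 and 2 together with 1 WT library. Splits that parted these 2 libraries gave 1 to 8. The high counts thus hold the difference of these 2 libraries from WT and are no reference for groupings without it. For AT lists camera gave 0 and the highest other 3, 10 splits as large. In the 5 libraries the real split gave 174 and the highest other 173, the split by replicate 1 above, and 1 split was as large, the real one.

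A hypothesis that junction abundance follows the FPKM of the host gene was not borne out to the size set in advance: over 2947 host genes the Spearman correlation of summed junction signal with FPKM was 0.189, below 0.5. The Gigyf2 host was at 22.4 FPKM in WT, while Nfix, with a junction of lower signal, was at 80.9. The correlation covers only genes with a listed junction, a narrowed range that can lower it. Medians between sets of genes went with the hypothesis. Hosts had a median of 16.5 FPKM, against 7.40 for tested genes that host no listed junction, a difference that was not tested. For a second hypothesis, that a junction's genotype difference follows its host's, the Pearson correlation across 6782 junctions was 0.0774, below the 0.2 set in advance. It was 0.0792 with host differences from the 5 libraries. These values cannot decide the hypothesis, since the junction differences had a median SE of 0.613 and few hosts changed, so noise alone can hold the correlation low. Genes and junctions are not independent replicates, and AT and CG values come from separate tables. Of the 174 called genes, 2 hosted a listed junction, C4b and Tgfbr2. The junction listed under C4b (chromosome 17, 34880706 to 34960185) had signals of 0.374, 0.456 and 3.74 in WT. In 5xFAD it had 7.80, 53.1 and 3.11 (limma adjusted p = 0.723). Its reads could be shared with the near-identical C4a. With no mm9 annotation used, whether the interval lies within C4b was not checked. It does not show a circular RNA of C4b. The Tgfbr2 junction (chromosome 9, 116038933 to 116040831) differed by 0.13 (SE 0.71), while Tgfbr2 itself rose by 1.19 in the 5-library fit.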
